A study of Homo sapiens with 10 samples.

How the data were processed

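Bulk RNA sequencing was analysed for 10 libraries of untreated human leukaemia and lymphoma cell lines: 1 library each of pure HL60, K562, SUDHL4 and THP1 cells, and 6 in vitro mixtures of these 4 lines. Per the labels, cells grew in RPMI with 10% serum, total RNA was taken at day 0 with a spin-column kit, and libraries were made either with a stranded total RNA kit for low input or with a stranded mRNA kit. The labels do not say which library was made with which kit, and they do not give the ratios of the mixtures. Each library was assigned to its group from its title. Every group holds 1 library, so nothing in these data measures the spread between replicates, and no p-value is given for a difference between libraries.

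The submitters' processing notes name HISAT2, featureCounts, Cell Ranger ARC 2.0.0 and the genome build hg19; which annotation and which settings were used is not given in the sources used here. The authors deposited 1 table of signal values for 20591 genes, listed by Ensembl gene ID, of which 16800 also carry a symbol. The deposited signal is on the scale of counts per 1000000 reads (CPM), but the columns do not sum to 1000000, so the library sizes had been rescaled between libraries by a method that is not given in the sources used here. Every value above 0 is a whole number of reads plus 0.5, multiplied by a constant step for its column; dividing by the step gave whole numbers, within a tolerance of 0.01, for 100% of the values above 0 in each of the 10 libraries. Values are called normalised CPM below. The recovered reads ran from 24985570 in mixture 5 to 36607612 in mixture 1, and the rescaled library size was between 0.903 times (HL60) and 1.10 times (mixture 3) the total of recovered reads. The gene with the fewest reads had 11 over the 10 libraries together, so genes with fewer reads did not enter. The design fixed before the data were examined had assumed plain CPM; the rules were applied to the deposited signal as they stood.

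A level of 1 read corresponded to between 0.0409 and 0.0594 normalised CPM, depending on the library. For a gene with 0 reads, the upper limit was set at 3 reads, which is between 0.0955 and 0.139 normalised CPM. Intervals of single levels are exact 95% Poisson intervals of the recovered reads. Intervals and limits of this kind cover counting error only, since reads from amplified libraries are not independent molecules.

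A gene was called enriched in a line when it had at least 5 normalised CPM there and its log2(value + 1) lay at least 2 above the highest of the other 3 pure lines, which is about 4-fold and less than the true ratio for low genes. A gene was called shared by a pair of lines when both passed that level and that margin over both remaining lines. For 22 gene lists written before the data were examined, holding 464 entries of which 393 distinct genes were measured, the median log2 difference between a line and the mean of the other 3 was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Genes named in the text are the 6 enriched genes per line with the largest margin among those at 50 or more, the 3 shared genes per pair with the largest margin, and members of the fixed lists as examples; any other gene is said to have been chosen after its values were seen. Genes without a symbol, XIST and genes of the Y chromosome are not named.

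The share of each line in a mixture was estimated by non-negative least squares on the 4 pure profiles over 100 signature genes per line, those with the largest margin among its enriched genes, leaving out all genes of the fixed lists. HL60 had only 104 candidates, so its signature reached down to a margin of 2.14 log2 units, against 4.10 to 4.64 in the other lines. The alternative of 200 genes per line could therefore not be met for HL60. Each gene was divided by its highest pure level, and the 4 coefficients were rescaled to sum to 100%. Intervals are 95% percentile intervals over 1000 bootstrap draws of genes within each line; they measure disagreement between genes, not replicate error. A share is a share of RNA, not of cells. A gene was called off the predicted profile when observed and predicted log2(value + 1) differed by at least 1 and either value was at least 5, the prediction being the coefficients times the pure profiles. The level of a line's marker list in a mixture was the median, over its members enriched in that line, of the mixture value as a percentage of the pure value. It was compared with the estimated share over the 6 mixtures by Pearson's r and Spearman's rho, with two-sided exact permutation tests over 720 pairings and Benjamini-Hochberg adjustment over the 4 lines.

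Transcript lengths, GC contents and gene positions were taken by Ensembl ID from GENCODE release 29, which uses the GRCh38 build, while the authors' build was hg19; positions are therefore those of GRCh38 alone. An annotated transcript was found for 19923 of the 20591 genes, 96.8%. The longest transcript of each gene was used.

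The calculations were tested on simulated libraries. For genes enriched in SUDHL4, with 200 genes of 20591 raised by a known factor, the rule found 100% at 6-fold and 0% at 3-fold, with 0 false calls at either. For 24 simulated shares over 400 signature genes, the largest error was 0.262 percentage points with counting error alone and 1.44 points with an added gene-wise error of 0.3 on the log2 scale; 23 of the 24 true values lay inside their intervals in the latter case and 20 of 24 in the former. In simulated versions of the 6 mixtures with counting error alone, 0 genes were off the predicted profile, and for mixture 2 the rule found 100% of 200 genes seeded at 3-fold and 0% of 200 seeded at 1.5-fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

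Alternatives fixed before the data were examined changed the number and weight of signature genes, the estimator and its scale, the scaling of the libraries, the pseudocount, the minimum level and the fold thresholds. Added after the data were seen were scaling by total reads, removal of a trend with transcript length and GC content, thinning of all libraries to the same total, and leaving out mixtures 2 and 5. The 15 mitochondrial-encoded genes of a fixed list had 0 members in the table. Single-cell data of the same study were not used here.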

Results

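The series concerns deconvolution, the estimation of how much each cell type contributes to a bulk measurement, and its 10 libraries provide a test case with 4 known sources. HL60 is a promyelocytic acute leukaemia line, K562 an erythroid line from chronic myeloid leukaemia in blast crisis, SUDHL4 a germinal-centre type diffuse large B cell lymphoma line, and THP1 a monocytic acute leukaemia line. Each was sequenced once alone, and 6 mixtures of unstated ratios were sequenced once each. The pure libraries held 33050514 (HL60), 34571443 (K562), 27166921 (SUDHL4) and 32278674 reads (THP1), and mixtures 1 to 6 held 36607612, 26953000, 27359691, 26902190, 24985570 and 31607384 reads. Levels are given as normalised CPM, reads per 1000000 after the authors' scaling between libraries. Between 8936 (SUDHL4) and 10274 genes (mixture 5) reached 5 normalised CPM. There are no replicates, so differences between libraries have no replicate check.

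The first question is which transcripts set each pure line apart. In HL60, 114 genes were enriched (58 with housekeeping scaling), the fewest of the 4 lines. The leading gene was MPO, the peroxidase of neutrophil granules, at 15646 normalised CPM (chromosome 17, 58269856 to 58280935 in GRCh38) against 9.88 in THP1, 0.212 in K562 and 0.129 in SUDHL4. It was followed by IGLL1, an immunoglobulin-like surrogate light chain gene, at 140.1 and CLC, the galectin of Charcot-Leyden crystals, at 56.9. CLC had 0 reads in the other 3 lines, so it was at least 442-fold higher in HL60, against a limit of 3 reads in a library. S1PR4 (55.3), CST7 (264) and IGSF10 (59.2) completed the 6 genes with the largest margins. Of 21 measured promyelocyte and granule genes, 6 were enriched in HL60, among them CEBPE, a regulator of granulocyte maturation (216 against 6.58 in THP1), EPX (31.0) and BPI (21.0). Another 6 were enriched in THP1, where the serine proteases and related granule genes AZU1 (1867 against 74.2 in HL60), CTSG (1486 against 77.2), ELANE (801 against 119) and RNASE2 (572 against 46.7) were higher. The list median was 3.67 log2 units above the mean of the other lines in HL60 and 3.48 in THP1, each above all 10000 random lists.

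K562 had 539 enriched genes, led by the embryonic and fetal globins HBE1 (2755), HBG2 (2126) and HBG1 (1299), of which HBG1 and HBG2 are near-identical copies whose individual values are uncertain. RHAG, a red cell membrane protein of the Rh complex, stood at 807 (chromosome 6, 49605158 to 49636884), ALDH1A2, a retinoic acid synthesis enzyme, at 924 and KRT18 at 621. Of 31 measured erythroid and megakaryocyte genes, 21 were enriched in K562, including the transcription factor GATA1 (236 against 1.32 in HL60). The transferrin receptor TFRC of that list was instead enriched in HL60 (1732 against 376 in K562), and LMO2 was highest in THP1 at 199. Cancer-testis genes, normally active in germ cells, were enriched in K562 for 12 of 16 measured, such as PRAME (1471 against 70.4 in HL60) and SSX1 (135). Families with near-identical copies, including MAGEA3 with MAGEA6 and the GAGE genes, are uncertain gene by gene. The list of stromal and epithelial markers, included as a check for other cell types, had 5 of 10 members enriched in K562, with KRT8 at 687, EPCAM at 117 and COL1A2 at 21.9. The list medians in K562 were 4.99 (erythroid), 5.16 (cancer-testis) and 2.30 log2 units (stromal and epithelial), each above all random lists.

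Antigen presentation genes ran low in K562. Of 12 class I genes, 7 lay at least 4-fold below the lowest of the other lines, with HLA-B at 0.24 against 88.2 to 765 elsewhere, while B2M was present at 368. The class I median was −3.98 log2 units, below all random lists. In the BCL2 family, which governs apoptosis, BCL2 was at 1.62 in K562 (95% counting interval 1.23 to 2.10) against 105 in HL60, 147 in SUDHL4 and 163 in THP1, and BCL2L1 was at 216 in K562 against 28.5, 58.7 and 35.4. The median of the 15 family members in K562 was −0.65 log2 units, above 0.56% of random lists.

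SUDHL4 had 417 enriched genes. MS4A1, which encodes the B cell antigen CD20, was at 2669 (chromosome 11, 60455752 to 60470760), with 0 reads in HL60 and THP1 and 0.0424, or 1 read, in K562. JCHAIN, the joining chain of polymeric antibodies, was at 1751 and IGHG4, an immunoglobulin heavy chain gene with close homologues, at 708. DTX1 (577), FCRLA (473) and CD27 (379) followed. Of 29 measured B cell and germinal-centre genes, 24 were enriched and 28 were highest in SUDHL4, with BCL6, the germinal-centre repressor, at 366 and PAX5 at 264; CR2 was the exception, at 0.826 in SUDHL4 and 1.2 in K562. Class II antigen presentation genes were highest in SUDHL4 for 13 of 13 and enriched for 12, such as CD74 (4045 against 229 in THP1) and HLA-DRA (852 against 5.67). In HL60 and K562, at most 1 of the 13 reached 5 normalised CPM. Medians were 5.86 log2 units for the B cell list and 6.47 for class II, above all random lists. Among 12 measured T and NK cell genes, LCK was enriched in SUDHL4 at 252 and CD3D in K562 at 14.6; the list median was lowest in K562, at −0.46 log2 units.

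THP1 had 589 enriched genes, more than K562 by this rule but fewer at 8-fold (326 against 329), at 2-fold (989 against 1080) and with a minimum level of 20 (311 against 312). The largest margins were those of TGFBI, an extracellular matrix protein (566, chromosome 5, 136028895 to 136063818), MS4A6A (355), BMP8B (732), AGT (214), TIMP3 (314) and NID1 (212). TGFBI had 0 reads in the other 3 lines and was at least 4401-fold higher in THP1. Of 32 measured monocyte genes, 19 were enriched in THP1, among them lysozyme LYZ (1078 against 42.3 in HL60), CSF1R, the receptor of the macrophage growth factor (256), and S100A9 (823 against 63.8); CD86 and LILRB1 were enriched in SUDHL4 instead. Of 11 measured HOXA cluster and cofactor genes, 4 were enriched in THP1: HOXA9 (19.8), HOXA10 (44.2), HOXA11 (27.5) and HOXA13 (25.1). HOXA7 was enriched in SUDHL4 (14.96). The list median was highest in SUDHL4, at 0.43 log2 units (above 98.1% of random lists, highest line for 4 of 11 members). In THP1 it was 0.21 (above 67.1%, highest for 6). Most members were low, with 5 of 11 at 5 normalised CPM or more in THP1 and 2 in SUDHL4. The mean difference was 1.79 log2 units in THP1 and 0.05 in SUDHL4, so median and mean ranked these 2 lines differently. In the interferon response list, 5 of 21 genes were enriched in THP1, such as MX2 (20.5 against 2.03 in HL60) and OAS3 (16.9 against 1.53), and its median of 1.13 log2 units exceeded 99.9% of random lists.

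Less specific programmes differed by smaller amounts. Mitotic genes were highest in SUDHL4 for 10 of 20 members (median 0.64 log2 units, above 99.98% of random lists) and ran low in THP1 (median −0.84, above 0.32% of random lists) and HL60 (−0.16, above 0.23%). With housekeeping scaling these medians were −0.35 and −0.81, so which line was lowest depended on the scaling. Cholesterol synthesis genes were highest in K562 for 10 of 16 members (median 1.09), as with HMGCS1 at 1109 against 146 to 694, and the glycolysis and hypoxia list had a K562 median of 1.09, with SLC2A3 at 264 against 28.98 in HL60. Both K562 medians were above all random lists. Signs for HL60 and THP1 in the cholesterol and S phase lists, and for HL60 in the stem cell, BCL2 family and housekeeping lists, turned with the scaling. So did THP1 in the T and NK cell and housekeeping lists. A scaling multiplies every gene of a library by the same factor, so these turns follow from it and are not particular to the lists. On the scale of log2(value + 1) it moves lists of low genes less. With housekeeping scaling the HL60 median went from 0.54 to −0.11 in the cholesterol list and from −1.86 to −1.89 in the erythroid list. S phase genes were highest in HL60 for 11 of 19 members. Their HL60 median was 0.45 log2 units at the deposited scaling, above 89.5% of random lists and within their 95% range (−0.04 to 0.55). It was −0.20 when the pure libraries were scaled to equal housekeeping levels. That scaling moved the median of all 11717 genes compared in HL60 from 0.08 to −0.53. In the stem and progenitor list of 22, MECOM (33.0), DNMT3B (118) and ARHGAP22 (16.1) were enriched in K562 and FLT3 (83.5) in THP1, with list medians between −0.50 (SUDHL4) and 0.24 log2 units (THP1). In the inflammatory list of 17, TNF (64.3), CXCL8 (69.3) and CCL2 (22.6) were enriched in HL60, while 2 members were enriched in SUDHL4 and 1 in THP1. The HL60 list median was 0.60 log2 units, above 99.97% of random lists, but 0.02 with housekeeping scaling. In the immediate-early and stress list of 20, BTG2 was enriched in SUDHL4 (188), FOS in THP1 (32.5) and the near-identical HSPA1A and HSPA1B in K562 (117 and 70.7), with a K562 median of 0.78. No member of the S phase or mitotic lists was enriched in any line, and of 27 housekeeping genes only TFRC was. Of 16 measured genes whose transcripts mostly lack a poly(A) tail, 4 histone genes were enriched in K562, led by H1-2 at 1008, with a K562 median of 0.53; single histone genes have close copies and are uncertain.

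The next question is which transcripts a pair of lines had in common against the remaining lines; 752 genes met this rule over the 6 pairs. The myeloid pair HL60 and THP1 shared the most, 312, of which 27 were in the fixed lists. Its leading genes were PRTN3, a granule protease (739.8 and 1489), APP (576 and 571) and PLAC8 (301 and 402). K562 and THP1 shared 197 genes, led by the creatine transporter SLC6A8 (212 and 485), IGF2BP2 (108 and 178) and FSCN1 (265 and 285). SUDHL4 and THP1 shared 114, among them IRF8, a transcription factor of B and myeloid cells (159.6 and 570.2), HLA-DRB1, whose close homologues make it uncertain (206 and 78.5), and TNS3 (75.9 and 98.2). K562 and SUDHL4 shared 60 genes (LSR, TSPAN13 and MYO1D), HL60 and SUDHL4 shared 41 (ABLIM1, MZB1 and PTPRCAP), and HL60 and K562 shared the fewest, 28, with the RNA-binding protein gene IGF2BP1 at 176 and 319.8, ITM2A at 86.3 and 111, and CCND2 at 147 and 30.6.

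**Figure D1:**
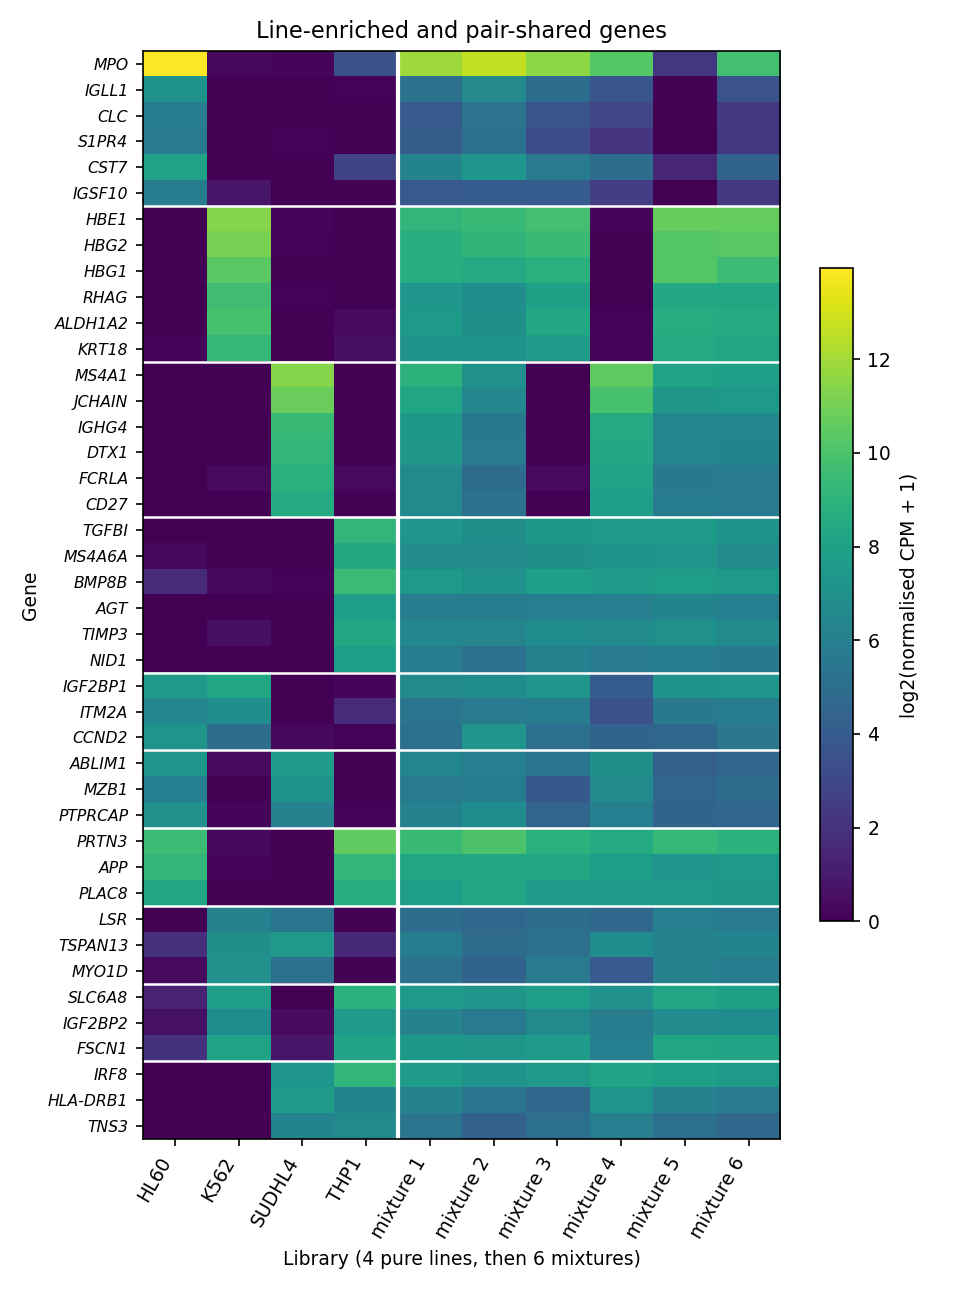
Levels of the 6 leading enriched genes per line and the 3 leading shared genes per pair (listed down the side, white lines between groups) in the 4 pure libraries and 6 mixtures (columns), as log2(normalised CPM + 1). MPO reaches 15646 in HL60 and 3.82 in mixture 5, and MS4A1 is at 0 in mixture 3.

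The central comparison asks how much of the RNA of each mixture came from each line. Mixture 1 was the most even, with 29.3% THP1 (95% interval over genes 28.6 to 29.95), 26.3% HL60 (25.3 to 27.2), 22.4% K562 (21.6 to 23.2) and 22.1% SUDHL4 (21.4 to 22.9). K562 and SUDHL4 could not be told apart there, with a difference of 0.261 percentage points (−1.03 to 1.501). The order of THP1 and HL60 in mixture 1 was not stable: HL60 came out larger under 3 of 11 alternatives, namely at 29.01% with the median-ratio estimator, 28.8% with total-read scaling and 35.5% with housekeeping scaling. Mixture 2 was mainly HL60, at 49.6% (47.7 to 51.5), with 24.6% THP1, 19.3% K562 and 6.50% SUDHL4 (5.90 to 7.13); over the alternatives the HL60 share ran from 48.4% to 60.6% and the SUDHL4 share from 3.87% to 6.96%. Among lineage genes, MPO was at 6511 and MS4A1 at 126 in mixture 2. For MPO 7251 was predicted there, and this gene lay below its prediction in all 6 mixtures.

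Mixture 3 held 39.2% K562 (38.3 to 40.1), 35.3% THP1 (34.5 to 36.1) and 25.5% HL60 (24.6 to 26.4), with SUDHL4 estimated at 0%. In mixture 4, SUDHL4 made up 57.6% (56.5 to 58.8), THP1 31.5% (30.4 to 32.6) and HL60 10.8% (10.1 to 11.5), with K562 at 0.0386% (0 to 0.111). Over the alternatives, these smallest shares ran from 0% to 1.95% for SUDHL4 in mixture 3 and from 0% to 2.62% for K562 in mixture 4, the highest with every gene at 5 or more in a pure line. Mixtures 5 and 6 were mainly K562, at 52.1% (50.6 to 53.7) and 52.3% (51.0 to 53.6). Their K562 shares differed by 0.178 percentage points (−0.739 to 1.14) and their SUDHL4 shares, 11.8% and 11.5%, by −0.278 (−0.894 to 0.244), which is within the disagreement between genes. They differed in HL60, at 0.478% in mixture 5 and 7.77% in mixture 6, a difference of 7.30 points (6.64 to 7.92), and in THP1, at 35.6% and 28.4%. The HL60 share of mixture 5 (95% interval 0 to 0.987) depended on the estimate and ran from 0% to 4.50% over the settings. It was 2.53% from unscaled values, 3.03% by median ratio and 4.50% with every gene. The HL60 share of mixture 6 ran from 7.17% to 10.97%. HBE1 was at 1655 in mixture 5 and 1603 in mixture 6, and MPO at 3.82 and 869. Over the 6 mixtures the unscaled coefficients summed to between 0.903 (mixture 3) and 0.956 (mixture 4). With housekeeping scaling, the HL60 share of mixture 3 became 35.7% and its THP1 share 27.0%, which turned their order.

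**Figure D2:**
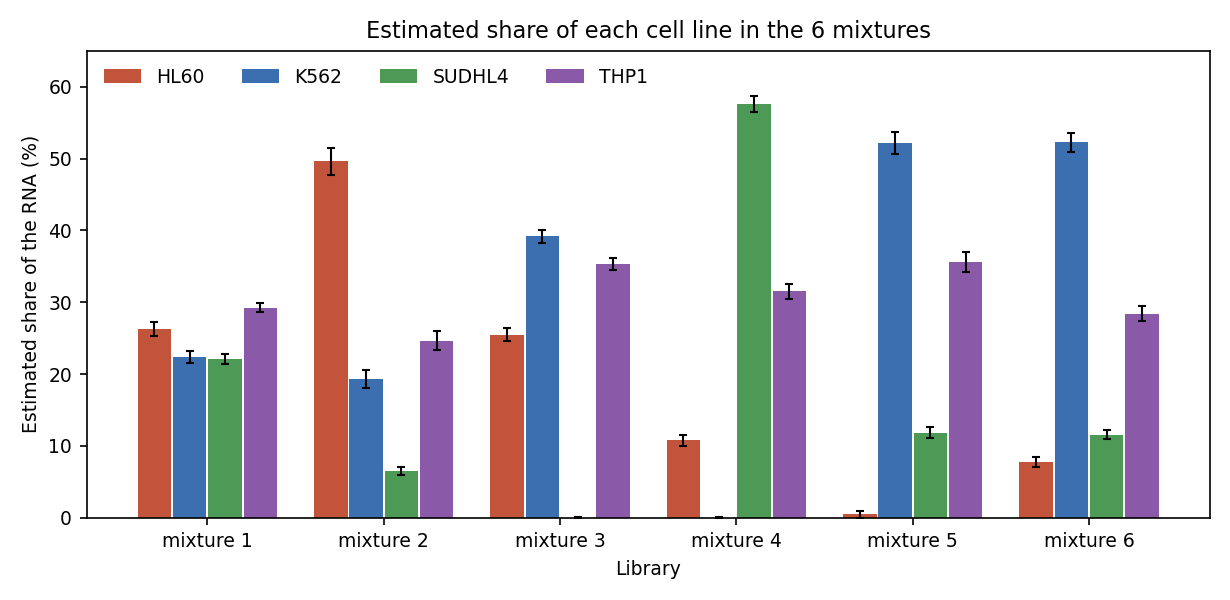
Estimated share of the RNA (%) of each line in each of the 6 mixtures. Bars are estimates from 400 signature genes and whiskers the 95% bootstrap intervals over genes; SUDHL4 in mixture 3, K562 in mixture 4 and HL60 in mixture 5 lie at 0%, 0.0386% and 0.478%.

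Genes with at most 3 reads each over the other 3 pure lines together gave a direct reading of the level of a line. No reads were subtracted for those other lines, so a few reads in a mixture may come from them. An interval above 0 is therefore not evidence that the line was present. In mixture 3, the 98 such genes of SUDHL4 had 49 reads in total, which is 0.0158% of their pure level (95% Poisson interval 0.0117 to 0.0210), and MS4A1, JCHAIN, DTX1 and CD27 had 0 reads. In mixture 4, the 176 such genes of K562 had 38 reads, 0.0152% of the pure level (0.0107 to 0.0208); HBE1 was at 0.133 (3 reads) and RHAG at 0 reads. In mixture 5, the 10 such genes of HL60 had 3 reads, 0.0351% (0.00724 to 0.103), with CLC and S1PR4 at 0 reads. MPO in mixture 5 was at 3.82 (95% counting interval 3.10 to 4.65), close to the 3.32 that the THP1 share alone would give. The signature estimate of 0.478% HL60 predicted 73.9 for MPO in mixture 5, so this gene departed from its prediction by −3.96 log2 units. Where a line was present, these percentages of the pure level compare with the coefficients before rescaling, where 1 is the pure level. They were 55.7% beside 0.551 for SUDHL4 in mixture 4 and 34.6% beside 0.354 for K562 in mixture 3, and the largest gaps were 62.1% beside 0.492 for K562 in mixture 5 and 59.4% beside 0.463 for HL60 in mixture 2. For K562 in mixture 6 the reading was 55.7% beside 0.499. By these genes K562 was thus higher in mixture 5 than in mixture 6, a gap that the estimated shares did not show. The erythroid list did not show it either, at 58.6% and 58.2% of its pure level.

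The marker lists took no part in the estimate and read other genes of the same libraries. Their members were kept by the same enrichment rule in the same pure libraries, so a relation with the shares follows largely from that choice. It does not check the shares against the mixed ratios, which are not given. Across the 6 mixtures, the B cell list correlated with the SUDHL4 share at r = 1.00 (exact permutation p = 0.00139, adjusted 0.00278; rho 1.00, permutation p = 0.00278, adjusted 0.00556), but with the mean log2 level of the list r was 0.811 (exact permutation p = 0.0875, adjusted 0.0875). For the promyelocyte list and HL60, r was 0.989 (exact permutation p = 0.00139, adjusted 0.00278; rho 1.00, permutation p = 0.00278, adjusted 0.00556). For the erythroid list and K562, r was 0.984 (exact permutation p = 0.00556, adjusted 0.00741; rho 0.886, permutation p = 0.0333, adjusted 0.0333). For the monocyte list and THP1, r was 0.843 (exact permutation p = 0.0361, adjusted 0.0361; rho 0.943, permutation p = 0.0167, adjusted 0.0222). The value 0.00139 is the smallest that 720 pairings can give. Without the 2 mixtures farthest from the median share, r over the remaining 4 was 0.997 (SUDHL4), 0.984 (HL60), 0.953 (K562) and 0.530 (THP1), so the THP1 relation rests on mixtures 2 and 5; with 4 mixtures no adjusted exact permutation p fell below 0.167. THP1 shares also spanned the narrowest range, from 24.6% to 35.6%. In single mixtures, the erythroid list stood at 58.6% of its pure level in mixture 5 and 24.7% in mixture 2, against K562 shares of 52.1% and 19.3%, which are rescaled to sum to 100% within a mixture, and coefficients of 0.492 and 0.180 before rescaling.

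**Figure D3:**
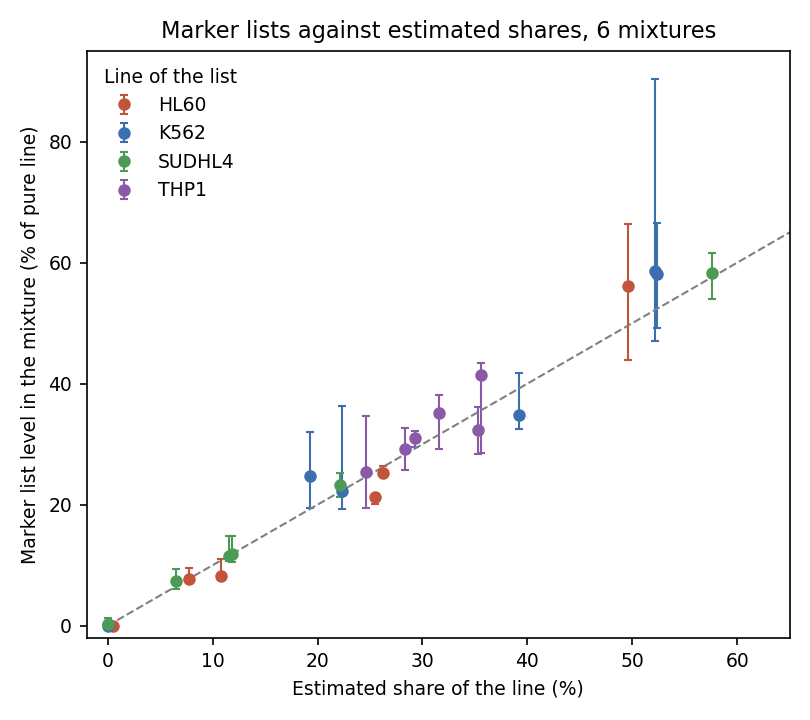
Level of each marker list in the 6 mixtures as a percentage of its level in the pure line (y axis) against the estimated share of that line (x axis, %, rescaled to sum to 100% within a mixture). Points are medians over the 24 (SUDHL4), 21 (K562), 19 (THP1) and 6 (HL60) enriched members, whiskers the interquartile range over members, and the dashed line marks equality; points run from 0% to 58.6%.

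The last question is whether the mixtures held transcripts that a sum of the 4 pure profiles does not give. Of 8942 genes at 5 or more in all mixtures, 0 were 2-fold above every pure line in all 6 mixtures, and of 7228 genes at 5 or more in every pure line, 0 were 2-fold below. In single mixtures, genes at 5 or more were counted when log2(value + 1) lay at least 1 above every pure line. They numbered 0, 7, 8, 3, 3 and 0 in mixtures 1 to 6. At low levels this rule asks for more than 2-fold. LOC119746555 in mixture 6, at 7.44 against 3.23, therefore did not pass. Of the genes that passed, the largest ratio was 10.4 for the pseudogene MTX1P1 in mixture 2 (8.18 against 0.788). Both genes were chosen after their values were seen. Observed and predicted log2 levels correlated at 0.977 (mixture 2) to 0.995 (mixture 3) across genes, which are not independent replicates. Genes off the predicted profile by at least 2-fold numbered 9, 126, 15, 22, 75 and 25 in mixtures 1 to 6, out of 10000 (mixture 4) to 10466 (mixture 5) compared; simulated counting error alone gave 0 in each. The counts depended on the settings, with 35 in mixture 3 and 54 in mixture 4 when shares came from every gene, and 70 in mixture 2 and 28 in mixture 5 with a minimum level of 20. In mixture 2, 53 were above and 73 below prediction, and in mixture 5, 57 above and 18 below. No gene was off in all 6 mixtures, and 40 were off in both mixture 2 and mixture 5, all 40 in the same direction, where independent lists would share 0.954. All mixtures were set against the same pure libraries, so part of the excess may come from the pure libraries. The departures of mixtures 2 and 5 correlated across genes at 0.858 (covariance 0.102), against 0.111 (covariance 0.000445) in simulated mixtures without departures set against the same redrawn pure libraries. Genes are not independent replicates. The simulation held counting error only, so it cannot show how much comes from a bias in the 4 single pure libraries. A high correlation was not particular to that pair: it was 0.766 for mixtures 2 and 6, 0.742 for 5 and 6, 0.615 for 1 and 5 and 0.574 for 1 and 2, while mixture 3 was at −0.216 with mixture 2 and −0.129 with mixture 5. Of the erythroid list, HBA1, HBA2, HBZ and KLF1 were off and above prediction in both mixtures (4 of 25 members compared in mixture 2 and 4 of 27 in mixture 5), and HBA2 also in mixture 1. Other lists shifted by as much in mixture 2, with medians of 0.34 (erythroid), 0.36 (promyelocyte), 0.35 (class I) and 0.41 log2 units (class II, 11 of 11 higher), and these 4 genes are short and rich in GC (640 to 1611 nt, 65.2% to 67.3%), the direction in which departures rose across all genes of these mixtures. In mixture 5, HBA1 was at 243, HBA2 at 127 and HBZ at 222 against predictions of 101, 45.7 and 92.6, and in mixture 2 they were at 78.8, 56.8 and 87.4 against 36.9, 16.8 and 34.0; these alpha-type globin genes include close copies.

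Departures varied with transcript length and GC content. In mixture 2, the shortest 10% of genes were above prediction by a median of 0.41 log2 units and the longest 10% below it by 0.36 (median −0.36). In mixture 5 the medians were 0.29 and −0.26. In mixture 3 the sign was opposite, with −0.05 for the shortest and 0.12 for the longest. Spearman's rho of departure with length across genes was −0.609 in mixture 2, −0.529 in mixture 5 and 0.365 in mixture 3. The rho with GC content was larger in size than that with length in mixture 1 (0.453 against −0.401), mixture 3 (−0.451) and mixture 4 (−0.406 against −0.326). Length and GC content together accounted for 14.9% (mixture 3) to 37.6% (mixture 2) of the variance of the departures. With the trend removed, 85 genes were off in mixture 2, of which 56 were among the 126 before, and 49 in mixture 5, of which 36 were among the 75 before; the others were off only after the removal.

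**Figure D4:**
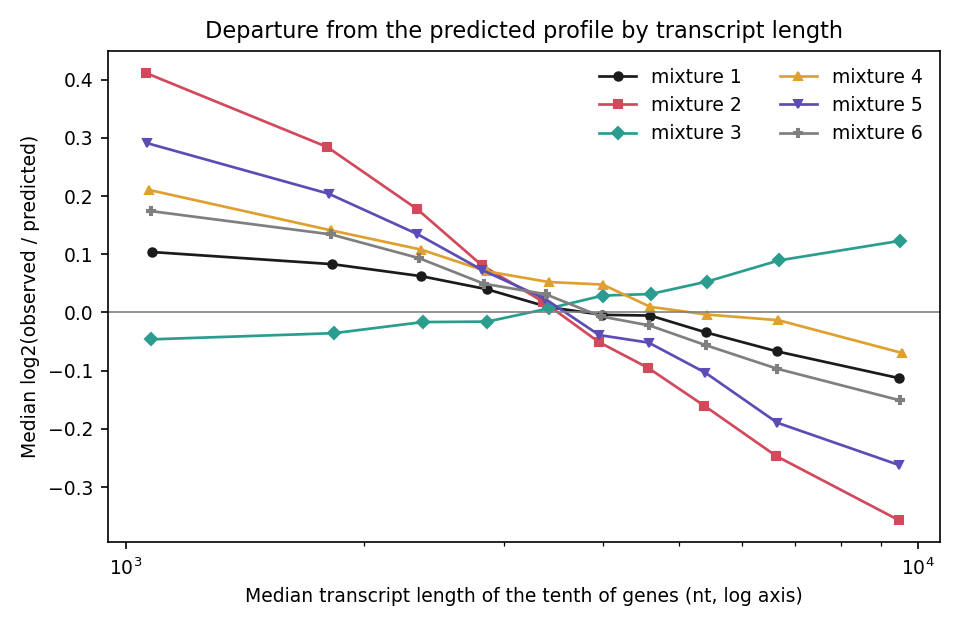
Median log2 ratio of observed to predicted level (y axis) for 10 groups of genes ordered by transcript length (x axis, nt, log scale), one line per mixture. Mixture 2 runs from 0.41 in the shortest group to −0.36 in the longest, and mixture 3 from −0.05 to 0.12.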

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

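Chosen after the data were seen were scaling by total reads, the removal of a trend with length and GC content, equal depth and leaving out mixtures 2 and 5; all other alternatives were fixed before the data were examined. No paired analysis was possible because each group holds 1 library. Of 66 alternative estimates of the shares over the 6 mixtures, 63 kept the same largest line, and the largest spread of any share over the settings was 12.3 percentage points. Depth limits a gene with 0 reads to between 0.0955 and 0.139 normalised CPM, for counting error only. Scaling the pure libraries to equal housekeeping levels shifted HL60 by −0.45 and THP1 by 0.42 on the log2 scale, and scaling by total reads shifted HL60 by −0.15 and mixture 3 by 0.14. Where a value below changed for another reason than the construction of the alternative, the cause was not tested.

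The largest line of mixture 1 turned from THP1 to HL60 under 3 settings, where THP1 had 28.7% by median ratio, 22.2% with housekeeping scaling and 28.3% with total-read scaling. Using every gene at 5 or more in a pure line gave largest shares of 30.4% (mixture 1), 54.1% (2), 56.1% (4), 49.1% (5) and 50.5% (6). The median ratio gave 37.9% (mixture 3), 56.1% (4), 50.4% (5) and 50.9% (6). Housekeeping scaling gave 60.6% (mixture 2), 37.3% (3), 56.6% (5) and 53.9% (6). Unscaled values gave 55.4% (mixture 2), 40.4% (3), 55.7% (4), 49.1% (5) and 49.1% (6). Without ribosomal protein genes the values were 28.6% (mixture 1) and 40.1% (3), and with total-read scaling 52.8% (2) and 37.5% (3).

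Counts of enriched genes in HL60, K562, SUDHL4 and THP1 and of genes shared by a pair moved by construction with the thresholds. They were 63, 287, 256, 294 and 339 with a pseudocount of 5, 43, 329, 238, 326 and 381 at 8-fold, and 393, 1080, 879, 989 and 1668 at 2-fold. With a minimum of 20, K562 had 312, THP1 311 and the pairs 368. With housekeeping scaling HL60 had 58. With no fold threshold, 6 genes lay below every pure line in all 6 mixtures. Genes off the predicted profile in mixtures 1 to 6 numbered 2, 47, 8, 10, 24 and 6 with a pseudocount of 5, and 3, 70, 6, 9, 28 and 7 with a minimum of 20. A pseudocount of 0.1 gave 15 in mixture 1 and 39 in mixture 6, shares from every gene gave 35 in mixture 3 and 54 in mixture 4, and removal of the length and GC trend gave 49 in mixture 5.

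Correlations of the marker lists with the shares lost their threshold over 4 mixtures, which cannot give an exact permutation p under 0.0417. Without the 2 farthest mixtures, r was 0.984 (HL60), 0.953 (K562), 0.997 (SUDHL4) and 0.530 (THP1). Without mixtures 2 and 5, r was 0.984, 0.987, 1.00 and 0.530. With the mean log2 level of the list, r for SUDHL4 was 0.811 (exact permutation p = 0.0875, adjusted 0.0875). A log2 level is not linear in the share, so r can fall by construction. With this level r was 0.885 for HL60 and 0.873 for K562, also lower, and 0.918 for THP1, which was higher.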

Other observations

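All tests of explanations in this part were chosen after the results were seen.

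Some single genes stood apart in the pure libraries. They were chosen after the data were opened, and genes that did not stand apart are not listed. No genotype or copy number data were used. CDKN2A and its neighbour on chromosome 9, MTAP, had 0 reads in both K562 and THP1, against 4.91 and 37.6 normalised CPM in HL60 and 25.3 and 24.3 in SUDHL4. In mixture 5, where HL60 was near 0%, MTAP was at 2.68 (95% counting interval 2.09 to 3.39), and the SUDHL4 share together with the HL60 estimate predicted 2.87. MYC was at 1292 in HL60 and 187 to 194 in the other lines, and reached 732 in mixture 2, where 688 was predicted. In K562, CRKL was at 565, NUP214 at 618 and ABL1 at 199.6, against 99.6 to 129, 119.7 to 169 and 71.2 to 98.5 in the other lines. In mixture 5, CRKL was at 306 (predicted 326). UBE2C, of the mitotic list, had 3 reads in K562 and lay at 33.0 to 97.8 in the other lines.

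Of 12 genes off the predicted profile in at least 4 mixtures, 3 are given here, chosen after their values were seen. DPYSL2, a microtubule regulator, was at 21.5, 29.8, 26.6 and 26.4 in mixtures 2, 4, 5 and 6, with predictions of 5.22, 12.97, 7.17 and 6.44. SNX27 was at 26.4, 18.0, 18.9 and 16.6 in the same mixtures against predictions of 10.4, 8.19, 6.18 and 6.76. REL, a subunit of NF-kappaB, was below prediction there, at 1.33, 20.2, 3.31 and 4.89 against 8.97, 43.1, 12.5 and 12.4. No cause was tested for these genes.

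Mixtures 2 and 5 had more genes off the predicted profile, 126 and 75, than the other 4 mixtures, where the highest count was 25. Transcript length and GC content may account for a part, and the trends removed here left a gap. With a linear trend removed the counts were 85 and 49 (27 at most in the other mixtures), of which 56 and 36 were off before. With medians of 100 classes of length and GC content removed they were 80 and 54 (26 at most). Both used the longest annotated transcript, which need not be the one expressed. A length or GC effect of another form is therefore not excluded. Depth does not account for it, since with all libraries thinned to the same total the counts were 126 and 79 against 25 at most, with 118 and 74 off before. Divided by the coefficient sum, the levels of 72 of these genes in mixture 2 and 52 in mixture 5 lay outside the range of the 4 pure lines (19 at most elsewhere). Errors in the shares alone cannot give such levels. Any excess over the range was counted, however small, so share errors may still account for part of these departures. F12 in mixture 5, chosen after its values were seen, was at 10.98 against 10.4 at most in a pure line, with 3.02 predicted. The gap did depend on the shares: with shares from every gene the counts were 147 and 85 against 35 in mixture 3 and 54 in mixture 4, so mixture 5 stood out less. Handling or library kit, which the labels do not tie to libraries, and a change of the cells in the pool stay open, and no biological explanation was tested.

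In mixture 3, 5 small structural RNAs lay above every pure line: RN7SK, an RNA that controls transcription elongation (122 against 56.0 at most), RMRP (31.1 against 9.82), SNORA73B (6.80 against 1.39) and 2 ribosomal RNA pseudogenes, all chosen after their values were seen. They were picked for lying at least 2-fold above every pure line. Their lowest ratio to the highest pure line, 2.17, was therefore fixed by the choice and is not a test. No shares of the 4 lines can give a level above every pure line. These RNAs also varied elsewhere: RN7SK was off by 1.00 and 1.09 log2 units in mixtures 2 and 5 and by −1.29 and −1.39 in mixtures 1 and 4, and RMRP by 1.19 in mixture 2 and 1.62 in mixture 5, where it was at 11.3 and above every pure line. In mixture 3 the shortest 10% of all genes lay below prediction (median −0.05), opposite to these RNAs. Removing the trend with length and GC content was therefore bound to raise their departure and is not a separate test. Their median departure was 2.85 log2 units after the removal and 2.73 before. More RNA without a poly(A) tail in this library stays open: the 11 measured histone genes of a fixed list, many of whose transcripts lack that tail, had a median log2 ratio to prediction of 0.77 in mixture 3 and 0.36 at most in the other mixtures, but this rested on the 8 below 5 normalised CPM (median 1.04), while the 3 above that level, H1-2, H2AC11 and H2BC5, were at −0.11, 0.11 and 0.17, and the whole list, over 5 members, had a median of 0.16, below mixture 2 (0.35) and mixture 5 (0.23). Whether the kit for this library differed is not stated in the labels, and no biological explanation was tested.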
